A study of Homo sapiens with 18 samples.

How the data were processed

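MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured in B cells of human tonsil on 1-colour Agilent human miRNA arrays, 1 array per sample. Per the labels, the 18 samples were 6 of centroblasts, 6 of naive and 6 of memory B cells, separated with magnetic beads and surface markers, and the 6 samples of each cell type came from different donors. The labels do not state whether the cell types shared donors, so the groups were compared as independent, with the replicate number as a block beside it. Total RNA was extracted with Trizol, and 100 ng of it was labelled with Cy3 for each array.

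Per the file headers, each array was scanned and quantified with Agilent Feature Extraction 9.5.3.1, while the processing notes of the submitters name version 9.5.1. Per the file headers, the values used here are background-subtracted spot intensities on a linear scale, with no scaling between arrays, and they equalled the software's background-subtracted intensity in every spot within 0.1%. The deposited per-miRNA intensities are the software's total gene signal, summed over the probes of a miRNA. The deposited matrix held the same intensities within 0.1%, also linear and unscaled. Viral probes on the design, 76 in miRNA entries, were left out of all tests.

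Each array held 13737 spots, of which 12784 were not controls, with 3 to 16 spots per probe. The human part comprised 723 miRNAs with 2125 probes, from 1 to 4 probes each. Spots well above background made up 14.24% to 22.54% of an array, and no spot was saturated. Intensities carry no counts, so only the number of arrays and the signal over background limit the precision.

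The spots of a probe were averaged without the spots the software marked as outliers, 5.07% to 6.55% of an array, and a probe was taken as detected where most of its spots were well above background by the software's flag. Every array was then divided by its own 75th percentile over the 172 probes detected on all 18 arrays and multiplied by the geometric mean of these percentiles. Scaled signals under 10.8 (3.44 on the log2 scale), the median over arrays of the lowest signal of a detected probe, were raised to that floor. Of several probes of a miRNA, the probe with the highest mean signal over all arrays was used. A miRNA was tested if it was detected on at least 6 of the 18 arrays, which left 192, of which 98 were detected on every array. A further 476 miRNAs were detected on no array.

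The log2 values were fitted with limma 3.58.1 in R 4.3.3, with the 3 cell types in 1 fit, and each pair was compared with its moderated two-sided test. Benjamini-Hochberg adjustment ran over the 192 miRNAs of each comparison, with a threshold of 0.05. Errors are the standard error (SE) of the limma fit for a difference and the standard deviation (SD) for a group of 6 arrays. Arrays at the floor have no spread, so the SD of dim miRNAs is understated. For a miRNA detected on no array of a group, the difference is given as a bound, taken on each array against the highest of the floor, the array's lowest detected signal and the probe's own signal. Such bounds apply to 7 called miRNAs of centroblasts against naive cells, 12 of centroblasts against memory cells and 1 of memory against naive cells.

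Before the data were examined, 22 lists of miRNAs were written down: genomic clusters, seed families, miRNAs abundant in leukocytes, and markers of other cell types. The 15 lists with at least 3 tested members were compared with the other tested miRNAs by camera with a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation was run beside it, and fry, which tests whether the members of a list move in one direction without comparing them with other miRNAs. The rule for names was set at the same time. It takes, in each comparison, the 10 largest called differences in each direction among miRNAs whose groups did not overlap. From each list it takes the 3 members with the smallest adjusted p and the brightest member that did not pass. It always takes miR-150, miR-155, miR-223, miR-28-5p, miR-181b, miR-146a, miR-125b, miR-9, miR-148a, miR-221, miR-222 and miR-17. The text names a part of the miRNAs this rule takes, chosen after their values were seen. Of the 12 always taken, miR-9 was detected on 2 arrays and was not tested.

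The alternatives were 4 other scalings, with the 75th percentile over all non-control probes, the median of the probes detected on all arrays, quantile normalization, and no scaling. At most 22.54% of an array's spots were well above background, so the percentile over all non-control probes can fall among undetected probes. Further alternatives were normexp background correction with an offset of 50, the per-miRNA total gene signal scaled as in the main fit, the deposited matrix as it stands, and the mean or sum of a miRNA's probes. The floor, the filter on dim miRNAs, the variance model, array weights, the pair of groups fitted alone and a minimum log2 difference of 1 were varied, and each array was left out in turn. The replicate number and the slide were each added as a fixed block. A block on scan time would be identical to the block on slide, since each slide had 1 scan time, so it was not run separately. The labels give the replicate numbers without saying what they stand for. Deviations from the group means were correlated over all tested miRNAs between same-numbered arrays. They ran from 0.18 to 0.53 in the 6 pairs of centroblasts and memory cells, all over 0.1, of which 4 were on the same slide. In the other comparisons 4 of 6 pairs each were over 0.1. The main fit leaves the replicate number out in every comparison, so its differences and p-values are unpaired, also for centroblasts against memory cells. Counts with the number as a block are given beside it. Added after seeing the data were a floor at the highest of the arrays' lowest detected signals, the omission of both arrays of slide 4, and the omission of the 3 arrays with over 30% of their signal in miR-923.

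Detected miRNAs per array and the 75th percentile signal were compared with a two-sided exact permutation test of 6 against 6 arrays, adjusted over the 3 pairs. The method was tested on simulated data of 192 miRNAs. With a true log2 difference of 0.5, 30%, 32.5% and 25% of the changed miRNAs were called in the designs of centroblasts against naive cells, centroblasts against memory cells and memory against naive cells. With a difference of 1, 70%, 82.5% and 60% were called, and with a difference of 2, 95%, 97.5% and 100%. Of unchanged miRNAs, 1 of 132, 2 of 72 and 1 of 132 were called. The simulated changes were divided evenly between higher and lower, and array brightness entered only as a factor that the scaling removes. The simulation therefore cannot show how often calls are false when changes run mostly in 1 direction or miRNA content differs between groups. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

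Coordinates are those of the probe targets, in genome build hg18 per the file headers. Members of a seed family with nearly the same sequence, such as miR-17 and miR-106a or miR-18a and miR-18b, can bind each other's probes, so their values are not fully separate. The entries miR-768, miR-886 and miR-923 of the array derive from other RNA classes (a small nucleolar RNA, a vault RNA and a fragment of ribosomal RNA) and are kept under the names the array gives them.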

Results

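Levels of miRNAs were measured in 3 B cell populations of human tonsil with 6 arrays each. Centroblasts, the dividing cells of the germinal centre, carried CD77. Naive cells, which have not met antigen, carried IgD without CD27, CD10 or CD38, and memory cells, which have, carried CD27 without CD10 or CD38. Between 14.24% and 22.54% of the spots of an array were well above background, and the total gene signal of an array lay between 40252 and 159300. All named miRNAs are the human (hsa-) entries of the array, and levels are log2 scaled signals with SD, n = 6 arrays per group unless stated.

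The 3 populations separated on the first 2 principal components of the 192 tested miRNAs, which held 52.6% and 26.7% of the variance. Within a group, the correlation between 2 arrays, taken across miRNAs, which are not independent replicates, ran from 0.954 to 0.987 for centroblasts, 0.963 to 0.991 for naive and 0.926 to 0.988 for memory cells. The entry miR-923 took 41.4% of the total gene signal in memory replicate 3, 39.5% in centroblast replicate 3 and 30.8% in centroblast replicate 5. The arrays lay on 5 slides, of which slides 1 and 2 each held 2 arrays of every group.

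**Figure D1:**
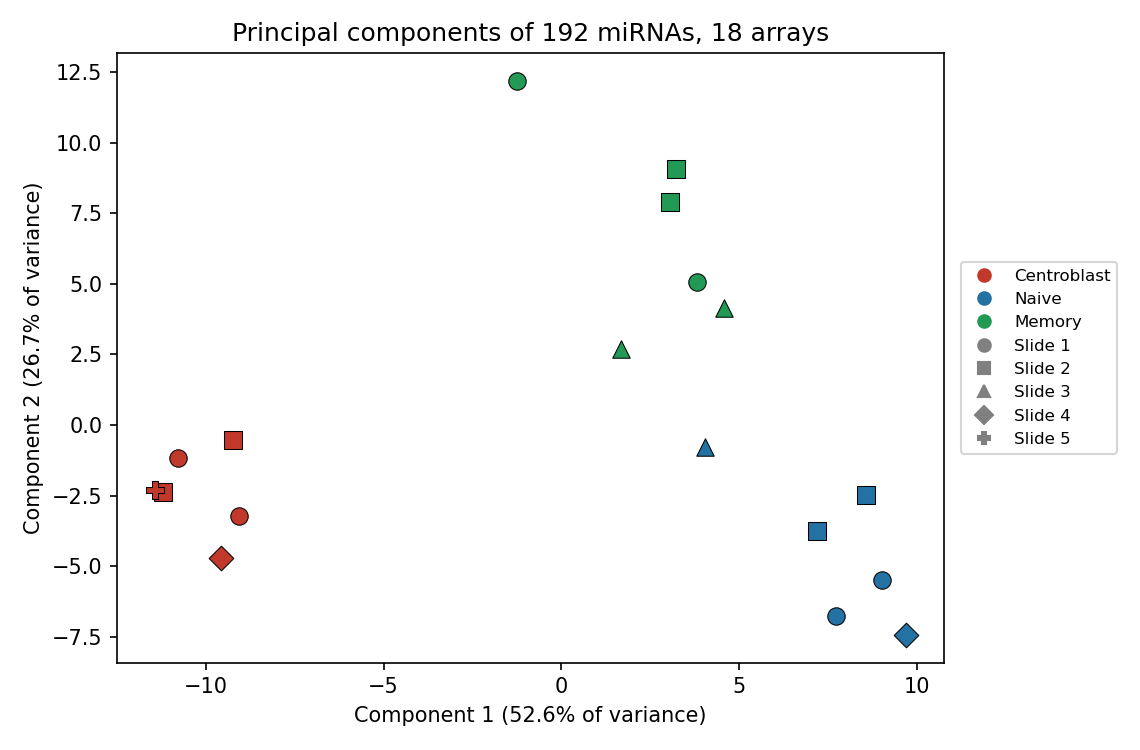
Principal components 1 and 2 of the log2 levels of 192 miRNAs, 1 point per array, with colour for the cell type and shape for the slide. Centroblasts lie apart on component 1 (52.6% of the variance), and naive and memory cells part mainly on component 2 (26.7%).

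Centroblasts were compared with naive cells to ask which miRNAs distinguish germinal centre B cells from cells that have not met antigen. Centroblasts held 18.7-fold less miR-150, a miRNA of resting mature lymphocytes that represses MYB, with 9.51 ± 0.65 against 13.73 ± 0.18. They held 9.08-fold less miR-223, best known from granulocytes and monocytes (7.33 ± 0.50 against 10.51 ± 0.42). In the other direction, miR-148a was 16.6-fold higher in centroblasts (8.06 ± 0.31 against 4.01 ± 0.86), though only 3 of the 6 naive arrays detected it and the other 3 lay at the floor. Centroblasts also held at least 10.7-fold more miR-125b, a repressor of the plasma cell factor BLIMP1, which was detected on 6 centroblast and 0 naive arrays.

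The oncogenic miR-17-92 cluster, a MYC target that promotes B cell proliferation and survival, rose in centroblasts with the scaling used here: 8 of its 8 tested members passed, and the same 8 when adjusted over the list alone. Its median log2 difference was 1.42 (camera adjusted p = 0.0054; adjusted p = 0.292 with an estimated correlation). Within it, miR-18a was 8.01-fold higher (7.93 ± 0.21 against 4.93 ± 0.56), miR-19a 4.13-fold and miR-17 3.18-fold (10.89 ± 0.23 against 9.23 ± 0.25). The smaller differences in the cluster depend on the scaling, with 0.55 for miR-20a* and 1.08 for miR-92a here. Without scaling, differences of miRNAs above the floor move by −0.74, the difference of the unscaled 75th percentile signal. Of the related clusters, 3 of 4 members of miR-106a-363 rose, among them miR-18b by 2.75 (1.76 on its other probe) and miR-106a by 1.73 on the log2 scale, and 3 of 3 of miR-106b-25, with the same counts adjusted over the list alone. Camera did not call either list (adjusted p = 0.108 and 0.136). In the miR-106b-25 cluster miR-93 was 4.20-fold higher, whereas the difference of miR-106b was 0.69 and turned to −0.25 with the 75th percentile over all probes and to −0.055 without scaling. Member miR-25 was higher by 1.04, but by 0.10 with the 75th percentile over all probes and by 0.30 without scaling, neither of which passed.

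In the miR-15/16 family, repressors of BCL2 and of cyclins, 5 of 8 members rose, also adjusted over the list alone, but camera did not call the list (adjusted p = 0.357). Member miR-15b was 4.37-fold higher and its partner strand miR-15b* at least 2.76-fold higher, while abundant miR-16 gave a difference of −0.21 (adjusted p = 0.18). Quantile normalization turned that of miR-16 to 0.040, whereas it was called lower with the 3 other scalings, at −1.15 with the 75th percentile over all probes, −0.95 without scaling and −0.67 with the median. Outside the lists that camera called, miR-28-5p, encoded in an intron of LPP, was 4.77-fold higher in centroblasts (8.84 ± 0.35 against 6.59 ± 0.04). A 5.37-fold higher level was measured for miR-146a, an NF-κB target that represses TRAF6 and IRAK1 (9.30 ± 0.17 against 6.88 ± 0.98). Levels of miR-193b and miR-365 were higher by 2.98 and 2.70 on the log2 scale, those of miR-130b by 3.02, of miR-30a by 2.33 and of miR-886-3p by 4.06. These are values of the brightest probe, and the detected probes ran from 0.72 to 2.98 for miR-193b and from 2.26 to 4.06 for miR-886-3p. The differences also depend on the floor, at which 3 of 6 naive arrays lay for each of miR-193b, miR-365 and miR-30a, 2 for miR-886-3p and 1 for miR-130b. The difference of miR-181b, a repressor of the mutator enzyme AID, was 0.71 (adjusted p = 0.00183), but −0.22 with the 75th percentile over all probes and −0.026 without scaling. For miR-155, which is needed for a normal germinal centre response, it was −0.05 (adjusted p = 0.85) and 0.21 with quantile normalization, but −0.99 with the 75th percentile over all probes and −0.51 with the median, both called.

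Several families fell in centroblasts. All 4 tested members of the miR-29 family, which represses DNA methyltransferases and MCL1, were lower, with a median of −1.33 (camera adjusted p = 0.0054; adjusted p = 0.292 with an estimated correlation), and miR-29a was 3.14-fold lower (10.45 ± 0.14 against 12.10 ± 0.17) beside miR-29c with a log2 difference of −1.45. All 3 members of the list of miR-26 and miR-101, repressors of the histone methyltransferase EZH2, fell, with a median of −1.42, a 4.56-fold lower miR-101 and differences of −1.42 for miR-26b and −1.15 for miR-26a. The 3 members of the cluster of miR-221 and miR-222, repressors of KIT and of the cell cycle inhibitor p27, fell with a median of −1.10, and miR-222 was 2.66-fold lower. Both lists had an adjusted p of 0.00532 with camera, and an adjusted p of 0.124 with an estimated correlation. Of 9 let-7 members, repressors of RAS and MYC, 6 fell and 2 rose (median −0.61, camera adjusted p = 0.0204, adjusted p = 0.305 with an estimated correlation). Members let-7g and let-7i fell by 1.41 and 1.36 on the log2 scale, whereas let-7e was higher by 1.89 than the floor, at which the brightest let-7e probe lay on all 6 naive arrays. Every one of these counts was the same adjusted over the list alone. Of 8 leukocyte-abundant miRNAs, 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0501), with miR-146b-5p lower by 1.40 on the log2 scale, a difference of −0.68 on its other probe, and a difference of −0.53 for miR-142-3p (adjusted p = 0.0701). That of miR-142-3p was called with 3 of the 4 other scalings, at −0.99 to −1.46, with normexp, the total gene signal, the deposited matrix, array weights, the pair fitted alone and the replicate number as a block, and without naive replicate 1 (−0.61) or 3 (−0.62) or memory replicate 3 (−0.55) or 6 (−0.53). Outside the lists, miR-361-3p and miR-768-3p fell, with log2 differences of −1.88 and −2.45. Both tested myeloid markers fell: beside miR-223, its partner strand miR-223* was detected on no centroblast array and was at least 1.38-fold lower, a difference that lost its call with double the floor and turned to 0.054 with normexp. With normexp the differences of miR-146b-5p and miR-221 shrank to −0.20 and −0.19 and were not called, and camera lost the list of miR-221 and miR-222 (shift against other miRNAs −0.52, and −1.59 here).

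In all, limma called 126 of 192 miRNAs, 91 higher and 35 lower in centroblasts. For 89 miRNAs the values of the 2 groups did not overlap, against 0.216% of miRNAs by chance. The median over all miRNAs was 0.45, and it was −0.26 with the 75th percentile over all probes, −0.14 without scaling, −0.13 with quantile normalization and 0.09 with the median. The share of higher miRNAs, 72.2%, was accordingly 32.1%, 39.1%, 45.7% and 51.3%. Under all 5 scalings, 33 miRNAs were called higher and 33 lower. These scalings include the 75th percentile over all probes, which can fall among undetected probes. The 5 lists that camera called lost that call without scaling and with the 75th percentile over all probes, and the let-7 and miR-29 families also with quantile normalization. The shift of a list, its median less that of the other miRNAs, changed little where scaling was left out or ran over all probes: −2.05 and −2.11 against −1.91 here for miR-26 and miR-101, −1.64 and −1.70 against −1.59 for miR-221 and miR-222, −1.87 and −1.86 against −1.82 for miR-29, −1.25 and −1.32 against −1.11 for let-7, and 0.84 and 0.79 against 1.03 for miR-17-92. With quantile normalization it was −1.31 for miR-29 and −0.15 for let-7. Within slides, all 126 differences kept their sign on slides 1 and 2 and 124 on slide 4, which held 1 array of each group. The 126 were called from arrays that include these, so kept signs cannot decide on a slide effect. Slide as a block gave 127.

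**Figure D2:**
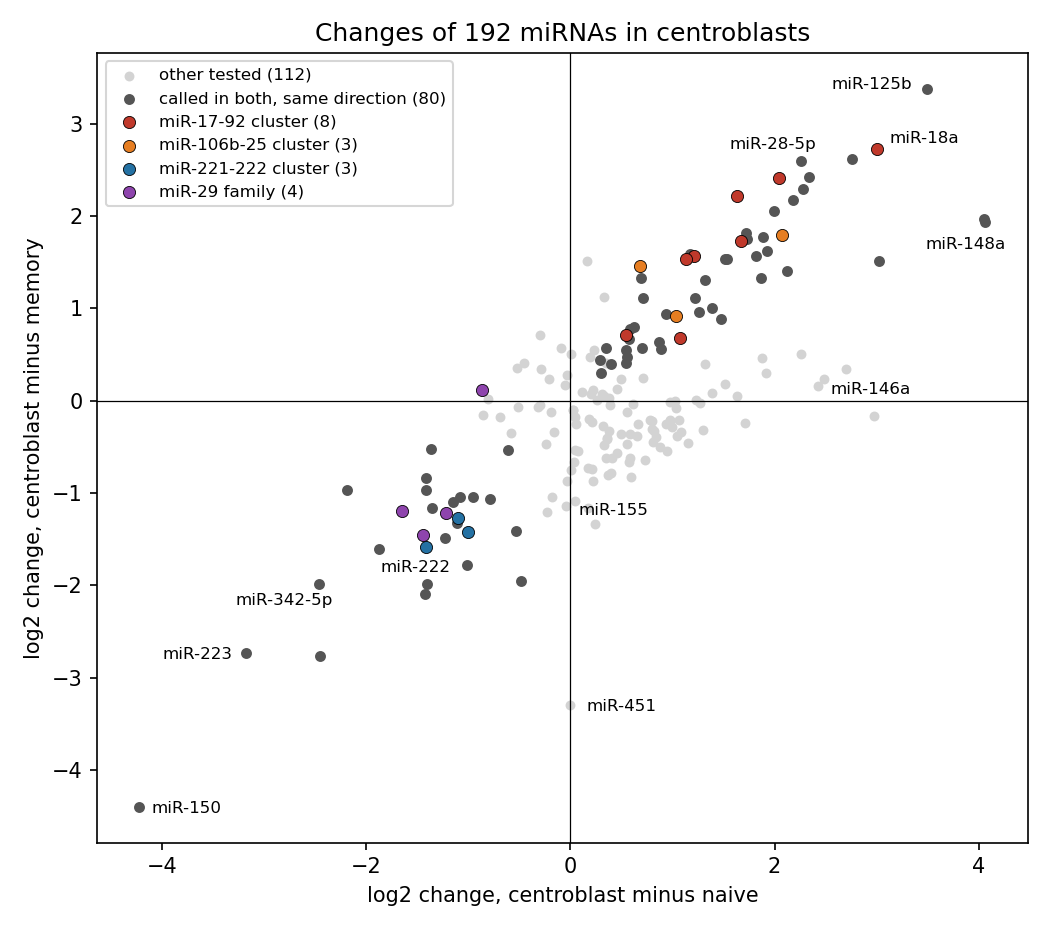
Fitted log2 differences of 192 miRNAs, centroblast minus naive on the horizontal and centroblast minus memory on the vertical axis, 1 point per miRNA, with 4 lists in colour. The 80 miRNAs called in the same direction in both comparisons lie at lower left and upper right, with the 8 members of the miR-17-92 cluster at upper right; miR-451 lies apart on the vertical axis.

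The comparison of centroblasts with memory cells asks the same of antigen-experienced resting cells. Again miR-150 was far lower in centroblasts, by 21.1-fold (9.51 ± 0.65 against 13.91 ± 0.52, adjusted p = 9.91e-11), and miR-223 was 6.64-fold lower. Centroblasts held 10.4-fold more miR-125b, a value that depends on the floor, since only 1 memory array detected it and the other 5 lay at the floor, and 6.03-fold more miR-28-5p. Its partner strand miR-28-3p was at least 3.65-fold higher, miR-30a at least 4.00-fold and miR-138 at least 3.38-fold, all detected on no memory array. Levels of miR-148a were 3.9-fold higher and those of miR-301a higher by 2.05 on the log2 scale, though 5 of 6 memory arrays lay at the floor, and by 0.36 and without a call with normexp.

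The miR-17-92 cluster and its relatives were higher here too. All 8 tested members of the miR-17-92 cluster rose, with a median of 1.65 (camera adjusted p = 0.000282; adjusted p = 0.177 with an estimated correlation). Its member miR-18a was 6.61-fold higher, miR-19a 5.31-fold and miR-17 3.32-fold. All 4 tested members of the miR-106a-363 cluster rose (median 1.67, camera adjusted p = 0.0090, adjusted p = 0.199 with an estimated correlation), as did all 3 of miR-106b-25 (median 1.45, camera adjusted p = 0.0363, adjusted p = 0.177 with an estimated correlation). Of these, miR-18b was higher by 2.62 (1.79 on its other probe), miR-106a by 1.76, miR-93 by 1.80, miR-106b by 1.45 and miR-25 by 0.92 on the log2 scale. In the miR-15/16 family 7 of 8 members rose, with a median of 1.13 (camera adjusted p = 0.0090, adjusted p = 0.199 with an estimated correlation), and miR-15b was 2.65-fold higher. The counts were the same adjusted over the list alone.

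The miR-181 family, regulators of lymphocyte development, had 2 members that rose and 1 that fell of 4, also adjusted over the list alone (camera adjusted p = 0.54). Member miR-181a was 2.85-fold higher and miR-181b higher by 1.11 on the log2 scale. The 3 tested members of the cluster of miR-221 and miR-222 fell (median −1.43, camera adjusted p = 0.0090, adjusted p = 0.177 with an estimated correlation), and miR-222 was 3.00-fold lower. In the miR-29 family 3 of 4 members fell, and 3 of 3 in the list of miR-26 and miR-101 (miR-29c by −1.45, miR-26a by −1.09 and miR-101 by −0.97), with the same counts adjusted over the list alone, but camera called neither (adjusted p = 0.109 and 0.0834). Of the miR-23-27-24 clusters 3 of 6 members fell, and 1 rose and 3 fell adjusted over the list alone. Within them miR-23a was 2.52-fold lower, miR-24 lower by 1.21 and miR-27a by 1.04 on the log2 scale. Of the leukocyte-abundant miRNAs 4 of 8 fell, also adjusted over the list alone (camera adjusted p = 0.109), among them miR-155 at 2.21-fold lower (9.80 ± 0.11 against 10.94 ± 0.42). Lower too were miR-146b-5p (−1.98, and −1.05 on its other probe), miR-342-3p (−1.16), miR-361-3p (−1.61), miR-625 (−1.96, and −1.11 on its other probe), miR-768-3p (−2.77) and let-7b (−1.49), and miR-139-3p, detected on no centroblast array, was at least 2.61-fold lower. Calls of miR-101 (−0.73 against −0.97 here), miR-26b (−0.60 against −0.84), miR-27a (−0.80 against −1.04) and let-7g (−0.73 against −0.97) ended without scaling. That call of miR-155 ended without scaling, where its difference was −0.90. For miR-146a the difference was 0.16 (adjusted p = 0.718), and −0.12 with the total gene signal. Among markers of other cells, the erythroid miR-451 was 9.83-fold lower in centroblasts (4.25 ± 0.96 against 7.55 ± 1.36) with overlapping groups and a log2 difference of −3.30, or −3.89 without memory replicate 3, and 1 of 2 myeloid markers fell. Of the 6 centroblast arrays, 3 detected miR-451 and 1 lay at the floor, so its fold depends on the floor.

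In total 105 miRNAs were called, 60 higher and 45 lower in centroblasts, or 116 with the replicate number as a block, 60 higher and 56 lower, and 74 had groups that did not overlap, against 0.216% by chance. This chance share takes the arrays as freely exchangeable, although same-numbered arrays of these groups deviated together. The median over all miRNAs was −0.07. With the 75th percentile over all probes 43.6% of the called miRNAs were higher, 46.4% with normexp and 40.2% with the total gene signal, against 57.1% here, and no called miRNA changed sign under any of the 5 scalings. Without scaling, camera lost its calls of the miR-106b-25 cluster and of the cluster of miR-221 and miR-222, with shifts against other miRNAs of 1.58 (1.53 here) and −1.32 (−1.38 here). The latter call was also lost with the 75th percentile over all probes (−1.41) and with normexp (−0.58), and that of the miR-15/16 family with normexp (0.40 against 1.25). Without the 3 arrays rich in miR-923, 92 were called, 44 higher and 48 lower. On slide 1, 104 of the 105 differences kept their sign, and on slide 2 all 105, but they were called from arrays that include these. Kept signs therefore cannot decide on a slide effect here either. Slide as a block gave 105.

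The 2 centroblast comparisons shared 80 miRNAs called in the same direction, 52 higher and 28 lower. Both lists use the same centroblast arrays. Independent lists of these sizes would share 28.4 and 8.20. With the centroblast arrays divided at random so that each comparison had its own 3, the medians were 48 and 27 over 20 divisions. How the shared miRNAs divided into higher and lower depended on the scaling. It was 26 higher and 40 lower with the 75th percentile over all probes, and 26 and 26 without scaling. With quantile normalization it was 34 and 37, and with the median 37 and 33. With the scaling used here, the shared miRNAs included miR-17, miR-18a, miR-28-5p, miR-125b and miR-148a on the higher side. On the lower side were miR-150, miR-223, miR-222, miR-29a and miR-342-5p. Of miR-342-5p, encoded in an intron of EVL, centroblasts held 5.51-fold less than naive cells, and its log2 difference from memory cells was −1.99.

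**Figure D3:**
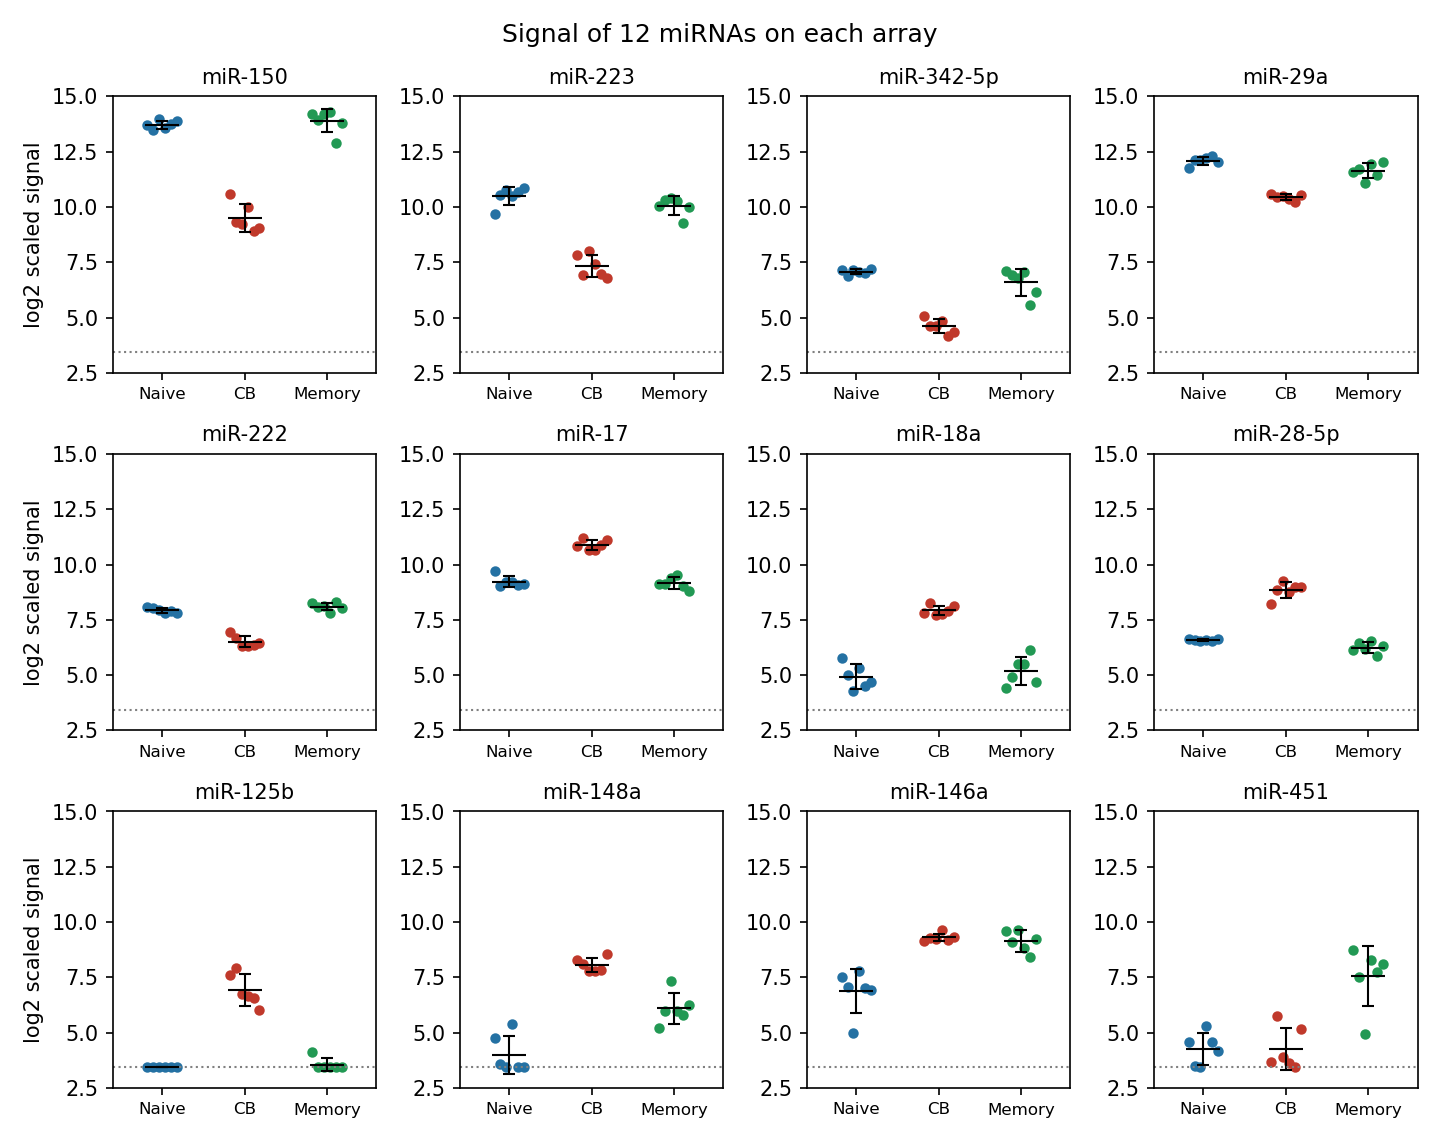
Log2 scaled signal of selected miRNAs on each of the 18 arrays, with points for arrays and bars for the mean and SD of the 6 arrays of a cell type. Centroblasts lie lowest for miR-150 (mean 9.51) and miR-223 (7.33).

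Memory and naive cells, the resting populations, were compared to ask what differs between cells with and without antigen experience. Memory cells held 9.79-fold more miR-451 (SE 0.55 on the log2 scale, adjusted p = 0.000162), a miRNA of the red cell lineage. Levels of the neighbouring genes miR-193b and miR-365 were 8.83-fold and 5.15-fold higher in memory cells, though the log2 differences of the 2 detected miR-193b probes were 0.83 and 3.14. Memory cells also held 4.80-fold more miR-146a (adjusted p = 7.62e-05) and 4.24-fold more miR-148a, a repressor of BACH2. For miR-193b, miR-365 and miR-148a 3 of 6 naive arrays lay at the floor, and for miR-451 1 did. All 5 of these were called higher under every scaling, and they were the only miRNAs that were. Of the 76 called higher here, 17 changed sign under at least 1 other scaling. Of the 29 called lower, 25 were called lower under every scaling and 0 changed sign.

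Other miRNAs higher in memory cells depended on the scaling. With the scaling used here miR-155 was 2.14-fold higher and miR-23a 2.97-fold, and 5 of 6 members of the miR-23-27-24 clusters rose, also adjusted over the list alone (median 0.92, camera adjusted p = 0.117). Without scaling, the difference of miR-155 was 0.11 and that of miR-23a 0.59, neither of which passed, and that of miR-24 turned from 0.98 to −0.0015. The oncogenic miR-21 was higher by 1.03, and by 0.043 without scaling. Calls of miR-21* (1.62), miR-22 (1.42), miR-494 (1.34), miR-625 (1.47) and miR-923 (1.58) also ended without scaling, though all stayed above 0. For miR-15b the difference of 0.72 turned to −0.11 with the 75th percentile over all probes and to −0.26 without scaling, and for miR-221 the difference of 0.42 was negative under each of the 4 other scalings.

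On the lower side, miR-181a was 2.54-fold lower in memory cells (7.25 ± 0.75 against 8.59 ± 0.26), miR-101 2.33-fold and miR-15a 2.01-fold. Members of other lists that were lower were miR-29b (−0.98), miR-106b (−0.77) and miR-363 (−0.80). The call of miR-363 ended with normexp (−0.25) and that of miR-29b without the filter on dim miRNAs, where more were tested, and the difference of miR-17* (−0.59) turned to 0.35 with normexp. The difference of miR-223 was −0.45 (adjusted p = 0.126), that of miR-181b −0.40 (adjusted p = 0.0702), that of miR-28-5p −0.34 (adjusted p = 0.0598) and that of miR-125b 0.12 (adjusted p = 0.708), and normexp turned those of miR-181b to 0.12 and miR-28-5p to 0.091. With the 4 other scalings miR-181b (−0.84 to −1.38) and miR-28-5p (−0.79 to −1.32) were called lower, and so was miR-223 with 3 of them (−0.90 to −1.43). Single arrays decided these calls as well, since miR-223 passed without naive replicate 1 (−0.61), miR-181b without memory replicate 2 (−0.50) or 4 (−0.46), and miR-28-5p without memory replicate 4 (−0.39) or centroblast replicate 1 or 3 (−0.34). In the miR-17-92 cluster 3 of 8 members fell, also adjusted over the list alone, with miR-20a lower by 0.40 and a difference of −0.06 for miR-17 (adjusted p = 0.728), which limma's array weights turned to 0.036. For miR-17 it was called lower with the 75th percentile over all probes (−0.89), without scaling (−1.05) and with the median (−0.51). In the list of miR-26 and miR-101 2 of 3 fell, and 2 of 4 in the miR-29 family, also adjusted over the list alone. Of 9 let-7 members 3 fell, and 2 adjusted over the list alone, and let-7i was lower by 0.84 on the log2 scale. Camera called none of the 15 lists here, where fry, which tests for a change in one direction and not against other miRNAs, called 7, and 6 had a camera p under 0.05 before adjustment. The levels of miR-150 (difference 0.17, adjusted p = 0.6) and miR-222 (0.17, adjusted p = 0.235) did not differ beyond the threshold with the scaling used here, and both differences were negative under each of the 4 other scalings. Both passed as lower in memory cells with the 75th percentile over all probes (−0.65 for miR-150 and −0.66 for miR-222) and without scaling (−0.81 for both).

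Here too 105 miRNAs were called, 76 higher and 29 lower in memory cells, and 38 had groups that did not overlap, against 0.216% by chance. The median over all miRNAs was 0.28, and it was −0.23 with the 75th percentile over all probes, −0.35 without scaling, −0.07 with quantile normalization and −0.03 with the median. The share of higher miRNAs, 72.4%, was accordingly 24.8%, 6.94%, 37.8% and 49.1%, and 89.2% with normexp. Within slides, 105 differences kept their sign on slide 1, 104 on slide 2 and 84 on slide 3, which held 1 naive array. Again the differences were called from arrays that include these, so kept signs cannot decide on a slide effect. Slide as a block gave 111. Without the 3 arrays rich in miR-923, 99 were called.

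**Figure D4:**
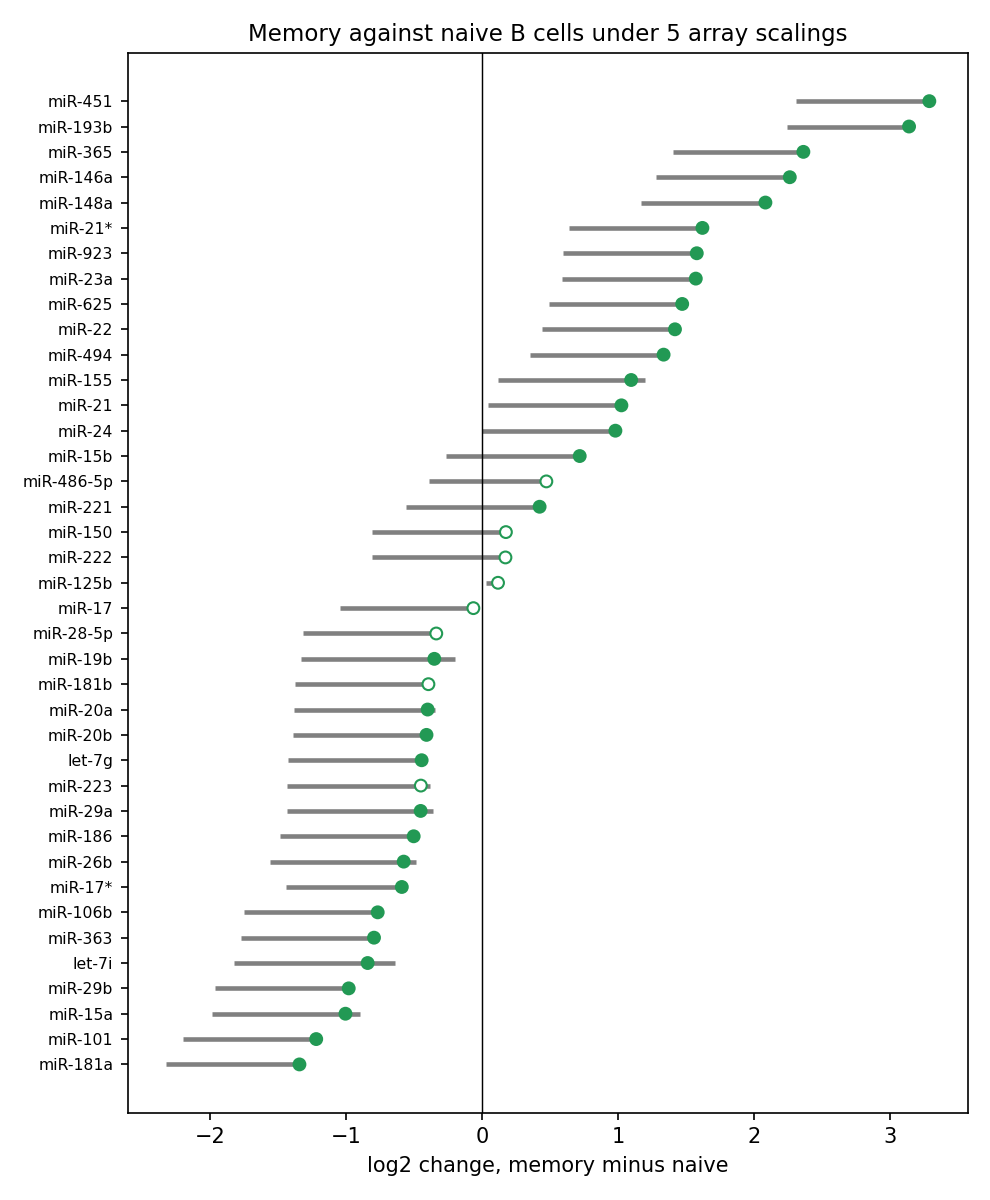
Log2 difference of named miRNAs, memory minus naive, on the horizontal axis, with the point at the scaling used here (filled if called, open if not) and the grey bar from the lowest to the highest value under 5 scalings. The bars of miR-24, miR-15b, miR-486-5p, miR-221, miR-150 and miR-222 reach or cross 0, while those of miR-451 and miR-181a stay on either side of it.

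The number of miRNAs detected per array was 175.5 ± 29.2 in centroblasts, 168.3 ± 28.5 in naive and 164.7 ± 15.2 in memory cells. No pair differed by more than the spread between arrays, with differences of 7.17, 10.8 and −3.67 and exact permutation p of 0.669, 0.437 and 0.792 (adjusted p = 0.792 for each), where the smallest possible p was 0.00216. The unscaled 75th percentile signal did differ. On the log2 scale it was 9.83 ± 0.53 on naive arrays against 9.09 ± 0.29 on centroblast arrays (exact permutation p = 0.0195, adjusted 0.0357) and 8.85 ± 0.65 on memory arrays (p = 0.0238 by the same exact test, adjusted 0.0357). The naive arrays exceeded the memory arrays by 1.58 on slide 1, 0.94 on slide 2 and 0.35 on slide 3.

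Probe targets of 9 of the named miRNAs lie in build hg18 as follows. That of miR-150 lies on chromosome 19 from 54695901 to 54695918, and that of miR-223 on chromosome X from 65155505 to 65155525. For miR-17 it runs on chromosome 13 from 90800879 to 90800895, and for miR-28-5p on chromosome 3 from 189889278 to 189889297. For miR-146a it runs on chromosome 5 from 159844960 to 159844978, for miR-148a on chromosome 7 from 25956067 to 25956086, and for miR-125b on chromosome 11 from 121475727 to 121475743. Those of miR-451 and miR-181a lie on chromosome 17 from 24212547 to 24212568 and on chromosome 1 from 197094860 to 197094874.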

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

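The tests of slide and of red blood cell RNA were chosen only after the results they address were seen.

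Among 192 groups of 6 values examined, 15 held an array whose gap to its nearest neighbour exceeded Dixon's 95% critical share of the group's range, where chance gives about 9.6. Memory replicate 3 was involved 4 times: its share of signal in the top miRNA, 41.4% against 17.5% on the next array (0.864), its miR-923 (0.878) and miR-494 (0.815) as the highest, and its miR-451 as the lowest (0.681). Memory replicate 5 was lowest for miR-150 (0.644), miR-223 (0.644), miR-26a (0.648) and miR-768-3p (0.626). In naive cells, replicate 1 was highest for miR-17 (0.720) and miR-20a (0.629) and lowest for miR-223 (0.702), and replicate 3 was lowest for miR-146a (0.684) and miR-26b (0.684). The other arrays apart from their group were memory replicate 4, highest for miR-20a (0.699), and centroblast replicate 2, highest for miR-130b (0.643). No explanation was tested for these single arrays.

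Most miRNAs called in memory against naive cells were higher (76 of 105) with the scaling used here, and few (5 of 72) without scaling, and the naive arrays were brighter before scaling. Within slides 1 and 2 all of the 76 were higher in memory cells (100% as the lower share). The 76 were picked as higher from arrays that include these, so this share cannot decide whether slide was the cause. The brightness difference was at least 0.94 on the log2 scale within both slides, and 0.35 on slide 3, which held 1 naive array. With slide as a block, 83 were called higher and 28 lower. The last 2 results argue against slide as the only source. A candidate explanation is signal that did not follow an array's miRNA signal and was raised by scaling on dim arrays. Such signal would give these miRNAs a lower slope on the log2 scaling factor within groups. Their median slope differed from that of other miRNAs by −0.31, which ran from −0.38 to −0.05 as arrays were left out. Slopes under −0.5 were found for 28.9% of the 76 and for 6.03% of the other miRNAs. The explanation thus stays open. Also open, as untested, are a true difference in miRNA content per unit of RNA and the cell types themselves.

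The same explanation was tested for the 91 miRNAs higher in centroblasts than in naive cells. Their median slope differed from that of other miRNAs by 0.069 (from −0.0039 to 0.10 as arrays were left out), whereas the explanation needs a lower slope. The slopes were those used for memory against naive cells, so they did not come from centroblast and naive arrays alone. Some of the 91, such as miR-125b and miR-15b*, lay at the floor on every naive array, where the level cannot follow the scaling factor. The test therefore cannot decide on the explanation, which stays open. A difference in miRNA content between the cell types was not tested and also stays open, since 25 of the 91 changed sign under at least 1 of the other scalings.

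Memory cells held more miR-451 (difference 3.29), an abundant miRNA of red blood cells, which may mark red cell RNA left in those samples despite the selection of CD27+ cells. Of the other erythroid markers, miR-486-5p differed by 0.47 with an upper 95% bound of 1.19, below 1.65, which is 50% of the change of miR-451, and miR-144 was detected on 0 arrays. The settings moved miR-486-5p both ways: it was called higher with array weights (0.95) and normexp (0.48), and its difference was −0.25 with the 75th percentile over all probes, −0.39 without scaling, −0.28 with quantile normalization and −0.042 in the deposited matrix. Because miR-486-5p lay near the detection floor in naive cells, this does not exclude red cell RNA, and the clause on the floor was added after the result was seen. Expression of miR-451 in memory cells themselves was not tested and cannot be told apart from red cell RNA here.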

How the results depend on the processing

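The settings chosen after seeing the data were the highest floor and the omissions of slide 4 and of the 3 arrays rich in miR-923. Over 41 settings the called miRNAs ranged from 66 to 143 for centroblasts against naive cells (126 here), 64 to 130 against memory cells (105) and 52 upward for memory against naive cells (105, with the most under normexp at 132 higher and 16 lower), and the miRNAs shared by both centroblast comparisons from 46 to 90 (80). Of the named and called miRNAs, 33 of 39, 37 of 46 and 8 of 31 kept call and direction in every setting that tested them. A miRNA that the filter of a setting left out was counted as kept in that setting. In memory against naive cells 13 did so apart from the setting that requires a log2 difference of 1. The replicate number as a block gave 135, 116 and 111 and changed no call of a named miRNA but that of miR-142-3p in centroblasts against naive cells, where camera called 6 lists with it instead of 5. Same-numbered arrays deviated together in all 6 pairs of centroblasts and memory cells and in 4 of 6 in each of the others (−0.39 to 0.53 over all 18 pairs), the same number was the best partner in 4 of 18, and the median over arrays of other groups was 0.19 on the same slide and −0.071 on other slides. In 8 of 45 list tests, none of them called, the median lay above 0 and camera pointed down, because camera compares with the other miRNAs. Signal over background limits the tested miRNAs other than the 98 detected on every array.

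Some changes of over 1.5 times in the counts came with fewer tested miRNAs or a stricter call. Testing only miRNAs detected on all 18 arrays gave 66, 64 and 56, with 46 shared, and a minimum log2 difference of 1 gave 77, 65 and 52, with 49 shared. With the same miRNAs and threshold, the counts also moved for the deposited matrix (81 for centroblasts against naive cells, 51 shared), normexp (69 for centroblasts against memory cells, 46 shared) and no scaling (52 shared). The matrix holds the total gene signal unscaled, and the same signal scaled gave 114 for centroblasts against naive cells and 75 shared. Array scaling is the only difference between these 2 settings. For normexp and no scaling the cause was not tested.

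Camera called 5, 5 and 0 lists in the 3 comparisons, and its calls depended on the setting. Fry asks whether a list's members move one way and not whether they differ from other miRNAs, so its 11, 12 and 7 lists answer another question. Centroblasts against naive cells gave 0 lists with an estimated correlation, with the 75th percentile over all probes and without scaling, 3 with the deposited matrix and with detection on all arrays, and 9 without a filter. Against memory cells it was 0 with an estimated correlation, 2 with detection on all arrays, 3 without scaling and with normexp, and 11 without a filter. Memory against naive cells gave 1 with only these groups fitted, 2 with normexp and 12 without a filter. The filter also changed the number of lists tested, to 11 with detection on all arrays and 21 without a filter, against 15 here. Without a filter the lists were also compared with miRNAs detected on no array, so these counts are not like for like. The cause of the changes in camera's calls was not otherwise tested.

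Changing the scaling factor of each array moves the log2 differences of all miRNAs above the floor alike. Without scaling they moved by −0.74 in centroblasts against naive cells and −0.98 in memory against naive cells. These are the differences of the unscaled 75th percentile signal, so turns of this kind do not set single miRNAs apart. For the other settings the cause was not tested. Directions turned as follows, in the order 75th percentile over all probes, no scaling and deposited matrix. In centroblasts against naive cells miR-106b gave −0.25 and −0.055 (not the matrix), and miR-181b −0.22, −0.026 and −0.0090. In memory against naive cells miR-150 gave −0.65, −0.81 and −0.84, miR-15b −0.11, −0.26 and −0.26, miR-221 −0.41, −0.56 and −0.58, miR-222 −0.66, −0.81 and −0.83, and miR-486-5p −0.25, −0.39 and −0.042, while miR-24 gave −0.0015 without scaling and −0.027 in the matrix. Quantile normalization gave 0.21 for miR-155 and 0.040 for miR-16 in centroblasts against naive cells, and −0.52 for miR-150, −0.11 for miR-221, −0.088 for miR-222 and −0.28 for miR-486-5p in memory against naive cells. The median scaling gave −0.27 for miR-150, −0.026 for miR-221 and −0.28 for miR-222. Normexp gave 0.054 for miR-223* in centroblasts against naive cells, and 0.35 for miR-17*, 0.12 for miR-181b, 0.12 for miR-186 and 0.091 for miR-28-5p in memory against naive cells. The total gene signal gave −0.12 for miR-146a in centroblasts against memory cells, and array weights 0.036 for miR-17 in memory against naive cells. Leaving out single arrays moved miR-155 from −0.20 to 0.074 in centroblasts against naive cells, above 0 without naive replicate 1. It moved miR-17 in memory against naive cells from −0.14 to 0.032, above 0 without naive replicate 1 (0.032) or memory replicate 6.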

Other observations

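The tests of other divisions of the arrays were planned before the data were examined, except the test over same-numbered pairs, which was chosen after the result was seen. Several fixed lists have not been described yet. In centroblasts against naive cells, 2 of 6 miR-30 members rose, 2 of 6 of the miR-23-27-24 clusters (1 adjusted over the list alone), 3 of 4 of the X-linked cluster of miR-188 and miR-532 with 1 that fell, and 2 of 5 of the 14q32 cluster. Both tested members of miR-125-99-100 rose, both of miR-148-152, the single tested miR-34 member and 1 of 2 epithelial markers, while 1 of 4 miR-181 members rose and 0 of 3 erythroid markers passed. In centroblasts against memory cells 3 of 6 miR-30 members rose, 2 rose and 5 fell of 9 let-7 members, 0 of 4 of the cluster of miR-188 and miR-532 passed, and 1 rose and 2 fell of 5 of the 14q32 cluster. There, too, 1 of 2 of miR-125-99-100 rose, 2 of 2 of miR-148-152, 1 of 1 of miR-34 and 1 of 2 epithelial markers. Except where stated, these counts were the same adjusted over the list alone, and camera called none of those it was run on, which leaves out miR-125-99-100, miR-148-152, miR-34 and the epithelial markers with fewer than 3 tested members each.

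In memory against naive cells, 3 of 4 members of the cluster of miR-188 and miR-532 rose and 1 fell, 3 of 5 of the 14q32 cluster rose, and 4 rose and 2 fell of 8 leukocyte-abundant miRNAs. The miR-106a-363 cluster had 2 of 4 that fell, miR-106b-25 1 of 3, miR-30 1 of 6 (0 adjusted over the list alone), and the myeloid markers 1 of 2. The miR-15/16 family had 2 that rose and 3 that fell of 8, miR-181 1 and 1 of 4, and the cluster of miR-221 and miR-222 1 of 3 that rose. Further, 1 of 2 rose in miR-125-99-100, 1 of 2 in miR-148-152 (1 rose and 1 fell adjusted over the list alone), 1 of 3 erythroid markers, and 0 of 1 in miR-34 and 0 of 2 epithelial markers passed. Stromal markers (11 on the array) and endothelial and platelet markers (2 on the array) had 0 members detected on enough arrays to be tested.

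The number of called miRNAs was set against other divisions of the 12 arrays of each pair into 6 and 6, with 100 of the possible divisions drawn, the real one included. Only 1 of 100, the real one, called as many in each comparison: 126 against at most 81 in the others for centroblasts against naive cells, 105 against at most 78 for centroblasts against memory cells, and 105 against at most 69 for memory against naive cells. Counts this high are thus unlikely under an arbitrary division of the arrays. With 100 of 462 possible divisions drawn, the smallest share that could be seen was 1 in 100. Arrays of the same slide or number also deviated together, so chance is not excluded. Of the 32 divisions of centroblast and memory arrays, these groups alone, that part all 6 same-numbered pairs, run after the pairing was seen, the real one called 104 and the others at most 27, and with the number as a block 111 and at most 1.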
